A study of Caenorhabditis elegans with 10 samples.

How the data were processed

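Gene expression was measured in 10 samples of total RNA from Caenorhabditis elegans, extracted with Trizol, labelled with biotin by 3' in vitro transcription and read on 1-colour arrays with Affymetrix-style probe sets. Samples were grouped by the labels into mek-1 fed (3), mek-1 fasted (3), mlk-1 fed (2) and mlk-1 fasted (2), and 0 columns of the table were left without a sample. The deposited values are linear intensity, 1 value per probe set and array, as summarised by the authors. The method of summary and normalization is not given in the sources used here. On every array the lowest value lies just above 16 and the highest value of all is 12763, and the array medians (70.5 to 74.9) lie close together. The design assumed log2 values and named log2(value + 16) as the scale for linear ones. That scale was used throughout, so a probe set at the floor reads 5, and changes of dim probe sets are compressed toward 0. Precision is limited by the number of arrays, and at the low end by signal over background.

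The table holds 22625 probe sets. The 77 array control probe sets were left out of the tests, which leaves 22548. Of these, 20766 pair with 1 gene symbol, 887 with several and 895 with none. Where 1 value per gene was needed, the probe set with the highest mean over all arrays was taken from those with 1 symbol (17118 genes, of which 2981 had more than 1 such probe set). Probe sets of a gene did not always move alike. For nhr-2 the others ran from -0.41 to 0.64 in the mean fasting effect against 0.62 for the probe set used, and for snb-1, unc-18 and ins-24 the other probe set changed less (0.07, 0.15 and 0.09). Probe sets whose ID ends in _s_at or _x_at can hybridise to several transcripts.

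Group means were fitted to all 10 arrays with lmFit and eBayes of limma 3.58.1 in R 4.3.3 (6 residual and 2.90 prior degrees of freedom). The 7 contrasts were fasted minus fed in each strain, the equal mean of these effects, their difference, and mek-1 minus mlk-1 in fed animals, in fasted animals and on average. P values were adjusted by Benjamini-Hochberg over all tested probe sets within a contrast, with a threshold of 0.05. The limma and camera tests were two-sided. Errors of changes are the standard errors of limma's moderated fit, and errors of levels are standard deviations. The effects of fasting in the strains were also compared across genes by Pearson and Spearman correlation, and the overlap of calls was set against the product of the counts over the number of genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

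The contrasts, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, apart from the later choices named as such. The 43 lists were tested with limma's camera at a preset inter-gene correlation of 0.01, on 1 probe set per gene, in 5 of the contrasts (not in the separate strain differences of fed and of fasted animals), with Benjamini-Hochberg adjustment over the lists of a contrast. An estimated correlation served as an alternative. Member counts are given over all probe sets and adjusted over the list alone. The lists cover the germline and early embryo, other tissues (body wall muscle, pharynx, intestine, neurons), lipid and carbohydrate use, mitochondria, protein synthesis and breakdown, stress and detoxification, immunity and cuticle, and signalling. They hold textbook genes and gene families taken by name.

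The rule for named genes takes up to 10 increases and 10 decreases per contrast among genes past the threshold whose groups overlap in no array (5 each way for the difference, without the overlap criterion). It adds up to 4 members per list past the threshold in the mean fasting effect, up to 2 in the mean strain difference, and always mek-1, mlk-1, kgb-1, jun-1, fos-1, vhp-1, acs-2, fat-7 and sod-3. List members outside this rule are named, without values, where 5 or fewer passed, and the sek-1 and R03G5.6 probe sets are named in the text. All of these were chosen after their values were seen.

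The alternatives were quantile normalization, median centring, leaving out the lowest 30% of probe sets by mean, a trended and robust variance, array weights, a fit of the compared groups alone, 1 probe set per gene, leaving out _s_at and _x_at probe sets, a minimum change of 2-fold, the replicate number as a block, constants of 1 and 64, the estimated correlation, the mean of a gene's probe sets, and leaving out each array in turn. Chosen after seeing the data were log2(value) without a constant and leaving out both mek-1 arrays numbered 3. Whether equal replicate numbers pair the fed and fasted samples was checked by correlating each array's deviations from its group mean. Within mek-1 the fed and fasted arrays of the same number correlated at 0.440, 0.675 and 0.573, each above the highest value with another number (-0.0459, -0.0226 and -0.282). Within mlk-1 the value was 0.352, and with 2 arrays per group the value for unequal numbers is its mirror image (-0.352). Across strains arrays of the same number correlated at 0.150 to 0.326. Numbers therefore pair the samples, and blocked counts of probe sets and shared genes are printed. In the contrasts between strains the block was the number shared across strains, where these correlations were lower and mlk-1 has no array numbered 3. For the lists, list members and families named the blocked value is given where the block ended a call or moved a count by over 1.5 times. Where 1 of 2 arrays was left out, the lone array was assumed to vary like the other groups. With 2 or 3 arrays per group, a search for single outlying values was not run. Gene families by name prefix were tested with a one-sided Fisher's exact test, a choice made after the data were seen.

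The fit was tested on simulated data with 200 changed probe sets among 22548, in 5 runs. At a 2-fold change it recovered 82.6% for fasting in mek-1, 71.4% in mlk-1, 88.8% for their mean, 52.9% for their difference, 78.3% for the strain difference in fed and 76.9% in fasted animals, and 92.0% for their mean. At a 1.5-fold change it recovered 65.7% for the mean fasting effect and 0% for the difference. False calls among all calls ran from 4.41% to 6.92%. The camera test called a list shifted by 0.5 in 5 of 5 runs and unshifted ones in 0 of 205 tests. In these runs the noise of each gene was independent, so they do not test the preset correlation on genes that vary together.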

Results

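Total RNA of Caenorhabditis elegans adults carrying a mutation in mek-1 or in mlk-1 was profiled on 10 single-colour arrays. MLK-1 and MEK-1 are successive kinases of a JNK-type MAP kinase cascade that ends in KGB-1. The labels name the mutated gene of each strain but no allele, and a wild type was not analysed here. Animals were transferred on adult day 2 to plates with the bacterial food OP50-1 (fed) or without it (fasted), and RNA was taken on adult day 4. There were 3 fed and 3 fasted arrays of the mek-1 strain and 2 fed and 2 fasted arrays of the mlk-1 strain, a number that limits the precision of each value. The labels do not say whether replicates came from separate cultures, so each p measures only the spread between these samples. Median intensity per array ran from 70.5 to 74.9, and 22548 probe sets were tested. The first principal component held 45.4% of the variance and parted fed from fasted arrays. The second held 19.7%, and both mek-1 arrays numbered 3 lay apart on it, at -30.1 (fed) and -30.9 (fasted). On the first component mlk-1 fed 1 lay nearer to the fasted arrays, at -10.9, than mlk-1 fed 2, at -24.1.

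The first question was whether the transcripts of the mutated genes differed between the strains. The mek-1 transcript differed by -3.51 ± 0.06 between the strains (mek-1 minus mlk-1, mean over fed and fasted animals, log2, SE; adjusted p = 1.4e-08, limma). In fed animals its level was 7.17 ± 0.10 (log2 intensity with the constant, SD, n = 3) in the mek-1 strain and 10.17 in each of the 2 mlk-1 arrays. A further probe set shared by mek-1 and F48E3.9 differed by -1.90 ± 0.08 (adjusted p = 5.8e-06). The signal left in the mek-1 strain changed by -0.77 ± 0.07 with fasting, against 0.26 ± 0.09 in the mlk-1 strain, and these effects differed by -1.03 ± 0.12 (adjusted p = 0.0244). The mlk-1 transcript did not differ past the threshold, at -0.19 ± 0.11 (adjusted p = 0.537) for the probe set used and -0.17 ± 0.10 (adjusted p = 0.553) for the other. The labels do not say which part of mlk-1 is altered, and where its probe sets lie relative to that part is not known, so the mlk-1 labels could not be checked this way.

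The main question was what 2 days without food did to the transcriptome in both mutants. The uncharacterised gene T22F3.11 rose most, by 4.46 ± 0.27 (log2, SE, mean of the effects in 3 against 3 mek-1 and 2 against 2 mlk-1 arrays), followed by F46C5.1, at 3.44 ± 0.28. Others with large increases were acs-2, an acyl-CoA synthetase of mitochondrial beta-oxidation, at 2.98 ± 0.43, hacd-1, a hydroxyacyl-CoA dehydrogenase, at 2.68 ± 0.22, and far-7, a fatty acid and retinol binding protein, at 2.40 ± 0.25. The bestrophin best-1 rose by 2.63, the aquaglyceroporin aqp-1 by 2.44 and C23G10.11 by 2.92. Among the largest decreases, the cathepsin A-like carboxypeptidase ctsa-1.2 stood at -4.65 ± 0.13, the invertebrate-type lysozyme ilys-5 at -4.50 ± 0.31, hrg-11.2 at -4.22 ± 0.10 and the saposin-like protein spp-4 at -4.01 ± 0.26. In mek-1 animals ctsa-1.2 went from 11.38 ± 0.34 fed to 6.53 ± 0.09 fasted (SD, n = 3). Further large falls were in sysm-1 (-4.16), bcf-1 (-3.99), C14C6.5 (-3.86), mbug-1 (-3.83) and K12H4.7 (-3.81).

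**Figure D1:**
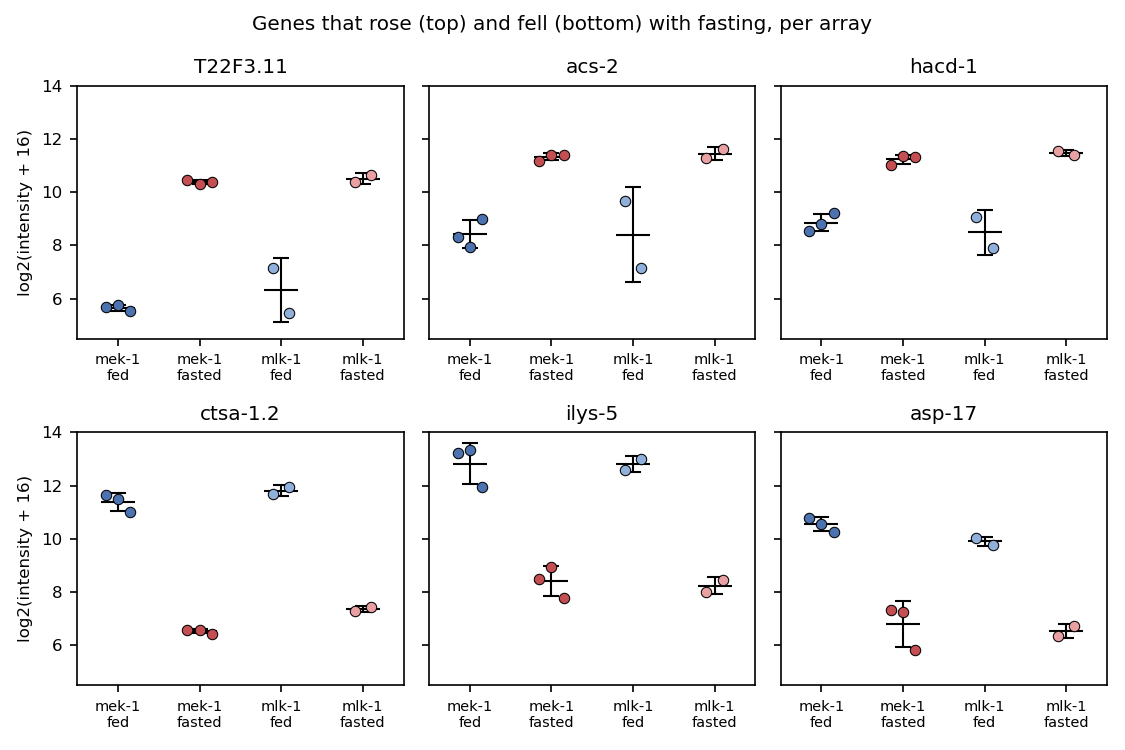
Level on each array, as log2(intensity + 16), of 3 genes that rose and 3 that fell with fasting in both strains; points are arrays and bars are the group mean ± SD. On every array T22F3.11 was higher and ctsa-1.2 lower in fasted than in fed animals of the same strain, and mlk-1 fed 1 had the highest T22F3.11 level of the fed arrays, at 7.16.

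In limma, 925 probe sets rose and 856 fell with fasting at an adjusted p under 0.05 (1781 of 22548). They stand for 720 and 689 genes. Changes of at least 2-fold went mainly down, with 376 lower and 63 higher. With the replicate number as a block, 2842 rose and 1660 fell (4502). The count was 1018 without mek-1 fasted 1, 1080 without mek-1 fasted 2, 1136 without mlk-1 fed 1 and 969 without mlk-1 fed 2. It was 913 without mlk-1 fasted 1 and 732 without mlk-1 fasted 2. The genes named with their values in the paragraph on T22F3.11 passed under every setting tried, the highest adjusted p being 0.0450, for aqp-1. The stearoyl-CoA desaturase fat-7 fell by 1.51 ± 0.27 (adjusted p = 0.0108), a call lost without mlk-1 fasted 1 (adjusted p = 0.0535). The superoxide dismutase sod-3 rose by 0.42 ± 0.08 (adjusted p = 0.0190), a call lost in 3 of 22 alternatives: without mlk-1 fed 1 (0.0664), without mlk-1 fed 2 (0.0624) and without mlk-1 fasted 1 (0.0786). The level of sod-3 in mek-1 ran from 7.04 to 7.35 on fed and from 7.09 to 7.24 on fasted arrays. In mlk-1 it was 7.14 and 7.17 fed against 8.18 and 7.93 fasted, so the rise came from mlk-1. In the cascade itself, kgb-1 (0.03 ± 0.10), its phosphatase vhp-1 (-0.01 ± 0.08), fos-1 (0.15 ± 0.08) and jun-1 (-0.36 ± 0.11) were not past the threshold. The jun-1 call was made with array weights (adjusted p = 0.0366) and with the block (adjusted p = 0.0058), and its highest adjusted p over the alternatives was 0.253.

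Among 43 gene lists, 25 passed limma's camera test for the mean fasting effect, 12 lower and 13 higher, and 0 passed with an estimated correlation. Of 100 splits of the arrays into 5 and 5, the real split included, 11 gave as many lists past the threshold. Lists of digestive and lysosomal genes were shifted lower. Of 26 lysosomal proteases, 14 fell and 0 rose (19 and 2 adjusted over the list alone), among them the aspartyl proteases asp-17 (-3.56 ± 0.28) and asp-1 (-1.92 ± 0.21) and the cysteine protease cpr-9 (-2.40 ± 0.36). The list's mean was -0.80 (adjusted p = 5.2e-15, and adjusted p = 0.183 with an estimated correlation). Of 15 intestine markers, which share asp-1 and cpr-6 with that list, 8 fell and 0 rose (9 and 0 adjusted over the list alone), including the P-glycoprotein pgp-1 (-1.21 ± 0.15). Their mean was -0.63 (adjusted p = 1.3e-08, and adjusted p = 0.183 with an estimated correlation). Lysozymes and antimicrobial peptides fell in 26 of 67 members (29 adjusted over the list alone), such as lys-1 (-2.45 ± 0.19) and lys-2 (-2.77 ± 0.41). Only ilys-3, spp-27 and spp-31 rose (4 adjusted over the list alone). The mean was -0.61 (adjusted p = 1.6e-12, and adjusted p = 0.183 with an estimated correlation). Of 220 C-type lectins, 26 fell and 5 rose (29 and 8 adjusted over the list alone), with clec-41 at -3.36 ± 0.22 and clec-174 at -2.83 ± 0.14. Their mean was -0.17 (adjusted p = 8.3e-05, and adjusted p = 0.434 with an estimated correlation). Their median was -0.0135, so part of the list carried the mean and the family as a whole moved little. The lectins that rose were clec-11, clec-47, clec-61, clec-82 and clec-196. With the block 11 lectins, 5 lysozymes or antimicrobial peptides and 2 lysosomal proteases were higher.

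Lists of structural genes were shifted lower as well. Of 142 cuticle collagens, 28 fell and 0 rose (77 and 0 adjusted over the list alone), with col-159 at -3.43 ± 0.54, col-160 at -2.79 ± 0.46 and col-183 at -2.69 ± 0.42. The list's mean was -0.75 (adjusted p = 1.4e-26, and adjusted p = 0.434 with an estimated correlation). Of 18 body wall muscle genes, 5 fell (tnt-2, unc-27, unc-54, tni-1 and pat-10; 9 adjusted over the list alone), with a mean of -0.60. That list passed at an adjusted p of 5.4e-07 (adjusted p = 0.434 with an estimated correlation), but tnt-2, unc-27, unc-54 and tni-1 were each lost under 3 or more alternatives, with adjusted p up to 0.175 for tni-1, and pat-10 was not followed through them. Array mek-1 fed 3 stood apart in both groups, at 1.19 above the mean of all arrays for body wall muscle and 0.93 for collagens. In the mek-1 strain the log2 ratio of 3' to 5' signal of the actin control probe sets had a mean of 1.66 in fasted and 1.31 in fed arrays. In mlk-1 these means were 1.54 and 1.51. The mek-1 means were also higher in fasted arrays for gapdh (0.960 against 0.835) and gly14 (0.658 against 0.414). They were lower in fasted arrays for ubiquitin (0.702 against 0.872) and catalase (1.986 against 2.102). The controls thus did not shift in one direction with fasting. Pharynx genes had 0 members past the threshold and a mean of -0.21 (adjusted p = 0.0130, and adjusted p = 0.555 with an estimated correlation). That call was lost without _s_at and _x_at probe sets (0.0622) and without mek-1 fed 3 (0.138), where the mean was -0.13. With the block 89 collagens, 11 body wall muscle genes and 4 pharynx genes were lower.

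Conjugating enzymes and lipid genes completed the lists shifted lower. Of 40 glutathione S-transferases, 10 fell, including gst-10 (-1.65 ± 0.18) and gst-27 (-1.31 ± 0.15), and gst-7 and gst-30 rose (11 and 2 adjusted over the list alone). Their mean was -0.20 and their median -0.0352 (adjusted p = 0.00184, and adjusted p = 0.434 with an estimated correlation). Of 64 UDP-glucuronosyltransferases, 9 fell, such as ugt-22 (-1.53 ± 0.19) and ugt-44 (-1.18 ± 0.11), and ugt-3, ugt-36 and ugt-57 rose (15 and 8 adjusted over the list alone). Their mean was -0.23 and their median -0.0721 (adjusted p = 0.00243, and adjusted p = 0.442 with an estimated correlation). Of 28 lipases, 5 fell (lipl-2, fil-1, fil-2, lips-11 and lips-14; 6 lower and 2 higher adjusted over the list alone), with lipl-2 at -1.48 ± 0.22 and fil-1 at -1.41 ± 0.21. The mean of the lipases was -0.19 (adjusted p = 0.0188, and adjusted p = 0.307 with an estimated correlation), a call lost without mlk-1 fed 1 (0.0644). Of 18 vacuolar ATPase subunits, vha-6 (-1.23 ± 0.11) and vha-12 (-0.51 ± 0.10) fell (4 lower and 1 higher adjusted over the list alone). The mean of these subunits was -0.16 (adjusted p = 0.00543, and adjusted p = 0.455 with an estimated correlation), a call lost without _s_at and _x_at probe sets (0.0958) and without mlk-1 fed 2 (0.0713). The vha-12 call was lost without mlk-1 fasted 1 (0.0741). Of 5 vitellogenins, the yolk proteins, vit-1 fell by 1.86 ± 0.39 (2 lower adjusted over the list alone), and the mean was -0.45 (adjusted p = 0.0143, and adjusted p = 0.434 with an estimated correlation). Without mlk-1 fed 2 the mean was -0.28 and vit-1 stood at -1.23. The list's call was lost without _s_at and _x_at probe sets (0.160), and the vit-1 call without mek-1 fasted 1 (0.0571), without mek-1 fasted 2 (0.0521), without mlk-1 fasted 1 (0.0874) and without mlk-1 fasted 2 (0.0844). With the block 19 UDP-glucuronosyltransferases were lower and 7 higher, 7 lipases were lower and 4 higher, and 4 vacuolar ATPase subunits were lower.

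Lists of mitochondrial energy genes were among those shifted higher. Of 48 respiratory chain genes, 12 rose and 0 fell (22 and 0 adjusted over the list alone), with the cytochrome c oxidase subunit cox-7C at 0.35 ± 0.05. Their mean was 0.21 (adjusted p = 3.8e-09, and adjusted p = 0.434 with an estimated correlation). Of 24 TCA cycle genes, 5 rose (idh-2, idha-1, cts-1, aco-1 and mev-1; 7 adjusted over the list alone), with the isocitrate dehydrogenase idh-2 at 0.60 ± 0.10 and idha-1 at 0.43 ± 0.06. The mean of these genes was 0.18 (adjusted p = 0.00213, and adjusted p = 0.434 with an estimated correlation). Lists of translation, proteasome and ribosomal genes were shifted higher with few members past the threshold. Of 38 translation factors 4 rose (5 adjusted over the list alone), led by eif-3.E (0.75 ± 0.12) and followed by eif-3.I, eif-2beta and eif-1.A, with a list mean of 0.16 (adjusted p = 0.00119, and adjusted p = 0.455 with an estimated correlation). Of 33 proteasome subunits pas-5, rpn-11, pbs-7 and rpt-5 rose (6 adjusted over the list alone), with a mean of 0.20 (adjusted p = 1.2e-06, and adjusted p = 0.455 with an estimated correlation). Of 63 cytosolic ribosomal proteins rps-13 alone passed (0 adjusted over the list alone), while the list's mean was 0.11 (adjusted p = 2.0e-06, and adjusted p = 0.434 with an estimated correlation). The calls of the translation, proteasome and ribosomal genes in this paragraph, eif-3.E aside, were each lost under 2 or more alternatives, with an adjusted p of up to 0.152, for eif-1.A. With the block 29 respiratory chain, 10 TCA cycle, 11 translation factor, 17 proteasome and 5 ribosomal protein genes were higher.

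Lists of ubiquitin ligase, germline and stress defence genes made up the remaining lists shifted higher. Of 27 Skp1-related and cullin genes of SCF ubiquitin ligases, 9 rose and 0 fell (13 and 0 adjusted over the list alone), such as skr-5 (0.76 ± 0.10) and skr-15 (0.70 ± 0.07), with a mean of 0.28 (adjusted p = 1.7e-04, and adjusted p = 0.434 with an estimated correlation). The skr-5 value joins 0.22 in mek-1 and 1.31 in mlk-1, while skr-15 rose by 0.67 and 0.74. Of 312 F-box proteins, 35 rose, such as fbxb-13 (0.57 ± 0.07), and 5 fell (42 and 10 adjusted over the list alone), namely fbxa-10, fbxa-51, fbxa-60, fbxa-105 and fbxa-190. Their mean was 0.09 (adjusted p = 0.00648, and adjusted p = 0.434 with an estimated correlation), a call lost without mlk-1 fasted 2 (0.0727). Of 26 histones, his-71 (0.68 ± 0.09), his-42 (0.45 ± 0.07), his-2, his-4 and his-6 rose and his-70 fell (12 and 1 adjusted over the list alone), with a mean of 0.20 (adjusted p = 8.1e-04, and adjusted p = 0.434 with an estimated correlation). The histone call was lost without _s_at and _x_at probe sets (0.803). Of 63 genes of the early embryo, which adults carry in the uterus, 9 rose and sdz-6 fell (14 and 1 adjusted over the list alone), with a mean of 0.14 (adjusted p = 0.00222, and adjusted p = 0.455 with an estimated correlation). DNA replication genes had 0 members past the threshold (5 higher adjusted over the list alone) and a mean of 0.15 (adjusted p = 0.0110, and adjusted p = 0.603 with an estimated correlation), a call lost without _s_at and _x_at probe sets (0.127), without mek-1 fed 3 (0.0865), without mek-1 fasted 2 (0.0585) and without mlk-1 fed 1 (0.0615). Autophagy genes had 0 members past the threshold (0 adjusted over the list alone) and a mean of 0.16 (adjusted p = 0.0173, and adjusted p = 0.574 with an estimated correlation), a call lost with array weights (0.0544), without mek-1 fed 3 (0.132) and without mlk-1 fasted 2 (0.0544). Of 16 antioxidant genes sod-3, sod-4, trx-2 and trxr-1 rose (5 adjusted over the list alone), with a mean of 0.24 (adjusted p = 0.00325, and adjusted p = 0.434 with an estimated correlation). The rise of sod-3 came from the mlk-1 arrays. Of 15 DAF-16 target genes 6 rose, among them the linker histone hil-1 (1.40 ± 0.25), and the lysozyme lys-7 fell (7 and 1 adjusted over the list alone). The hil-1 call was lost without mlk-1 fasted 1 (0.0595). Their mean was 0.47 (adjusted p = 0.0109, and adjusted p = 0.475 with an estimated correlation). Array mek-1 fed 3 stood apart in this list, at -1.02 from the mean of all arrays, and without it the list's mean in mek-1 alone went from 0.45 to 0.15 (adjusted p = 0.229) and that over both strains to 0.32 (adjusted p = 0.0222). With the block 15 Skp1-related and cullin genes, 14 histones, 18 early embryo, 7 DNA replication and 7 autophagy genes and 10 DAF-16 targets were higher. Of F-box proteins 65 were then higher and 15 lower.

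The other 18 lists were not past the threshold for fasting as a whole, though single members were. Of 39 fatty acid oxidation genes, acs-2, hacd-1 and ech-7 rose and the acyl-CoA oxidase acox-1.5 fell (4 and 3 adjusted over the list alone). Here the median (0.03) and mean (0.06) were above 0 while the test's direction was down (adjusted p = 0.483). In fatty acid synthesis and desaturation (mean 0.11, adjusted p = 0.292) the elongase elo-6 rose by 1.08 ± 0.09, with let-767, while fat-7 fell (2 and 1 adjusted over the list alone). Of 9 lipid-binding proteins (mean -0.24, adjusted p = 0.0943), lbp-5 (-0.89 ± 0.14), lbp-2 (-0.75 ± 0.10) and lbp-7 fell (3 adjusted over the list alone). The pyruvate kinase pyk-2 rose by 0.81 ± 0.13 in glycolysis (mean 0.13, adjusted p = 0.176; 2 adjusted over the list alone). In the glyoxylate cycle and gluconeogenesis (mean 0.42, adjusted p = 0.176; 3 adjusted over the list alone) it was pck-2 that rose, a call lost without mlk-1 fed 2 (0.0540), without mlk-1 fasted 1 (0.0521) and without mlk-1 fasted 2 (0.0536). Among trehalose and glycogen genes the glucosidase genes aagr-1 (-1.83 ± 0.19) and aagr-2 (-1.59 ± 0.20) fell with tre-3, and aagr-4 rose (2 higher and 3 lower adjusted over the list alone). The median of that list was 0.02 and its mean -0.19, with the test's direction down (adjusted p = 0.340). Of 73 cytochrome P450s, 7 fell, such as cyp-13A2 (-0.93 ± 0.10), and cyp-13A1, cyp-13B2 and cyp-33C5 rose (8 and 4 adjusted over the list alone), with a median of 9.0e-04, a mean of -0.06 and a direction of down (adjusted p = 0.107). With the block 6 fatty acid oxidation genes were lower, while 5 genes of fatty acid synthesis, 3 each of glycolysis, the glyoxylate cycle and trehalose and glycogen, 1 lipid-binding protein and 10 cytochrome P450s were higher.

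Signalling and stress lists without a call also held members that moved. Of 16 heat shock genes 6 rose, including hsp-16.2 (0.90 ± 0.16), and hsp-17 fell (6 and 3 adjusted over the list alone), with a mean of 0.31 (adjusted p = 0.0825). The level of hsp-17 in mlk-1 was 9.33 and 10.18 fed and 9.50 and 9.71 fasted, so its fall came from mek-1. Of 24 insulin-like peptides, ins-7 fell (-2.32 ± 0.25) and ins-11 (0.95 ± 0.12), ins-17, ins-23, ins-24 and ins-35 rose (6 higher and 1 lower adjusted over the list alone; mean 0.05, adjusted p = 0.255). The ins-11 value joins -0.06 in mek-1 and 1.97 in mlk-1, effects that differed past the threshold (adjusted p = 0.0256, limma). Of 83 neuropeptides (mean 0.05, adjusted p = 0.819), nlp-51 (1.52 ± 0.23), nlp-35, nlp-52 and nlp-99 rose (10 adjusted over the list alone) and 7 fell (9 adjusted over the list alone). Those that fell included nlp-29 (-1.19 ± 0.17) and nlp-31 (-1.06 ± 0.17), which encode antimicrobial peptides of the epidermis. Of 259 nuclear hormone receptors 13 rose, led by nhr-21 (1.23 ± 0.10), and 0 fell (12 and 0 adjusted over the list alone; mean 0.07, adjusted p = 0.269). Among 20 neuronal genes (mean 0.06, adjusted p = 0.747) unc-18, snb-1 and ric-19 rose and unc-25 fell (3 and 1 adjusted over the list alone). The JNK-type and p38 pathway list (mean 0.07, adjusted p = 0.725; 1 higher and 2 lower adjusted over the list alone) had dlk-1 and mek-1 lower, and the ER unfolded protein response list (mean 0.11, adjusted p = 0.0943; 1 adjusted over the list alone) had sel-1 higher. The mek-1 transcript changed by -0.77 in the mek-1 strain, where its signal was already low, and by 0.26 in mlk-1, so its fall was not shared. Lists with 0 members past the threshold, and 0 adjusted over the list alone, were oocyte and eggshell (mean 0.08, adjusted p = 0.337), sperm (-0.00318, adjusted p = 0.395), meiosis and germ granules (0.06, adjusted p = 0.849) and mitochondrial stress (0.05, adjusted p = 0.939). With the block 25 neuropeptides, 30 nuclear hormone receptors, 4 JNK-type and p38 pathway, 3 unfolded protein response, 5 meiosis and germ granule and 2 oocyte and eggshell genes were higher, and 1 each of sperm and mitochondrial stress. Lower with the block were 7 nuclear hormone receptors, 3 heat shock and 2 neuronal genes. List members outside the rule for named genes were not followed through the alternatives. Over all 282 results on named genes, 102 were lost without mlk-1 fasted 2, 91 without mlk-1 fasted 1, 75 without mlk-1 fed 2 and 70 without mek-1 fasted 1.

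**Figure D2:**
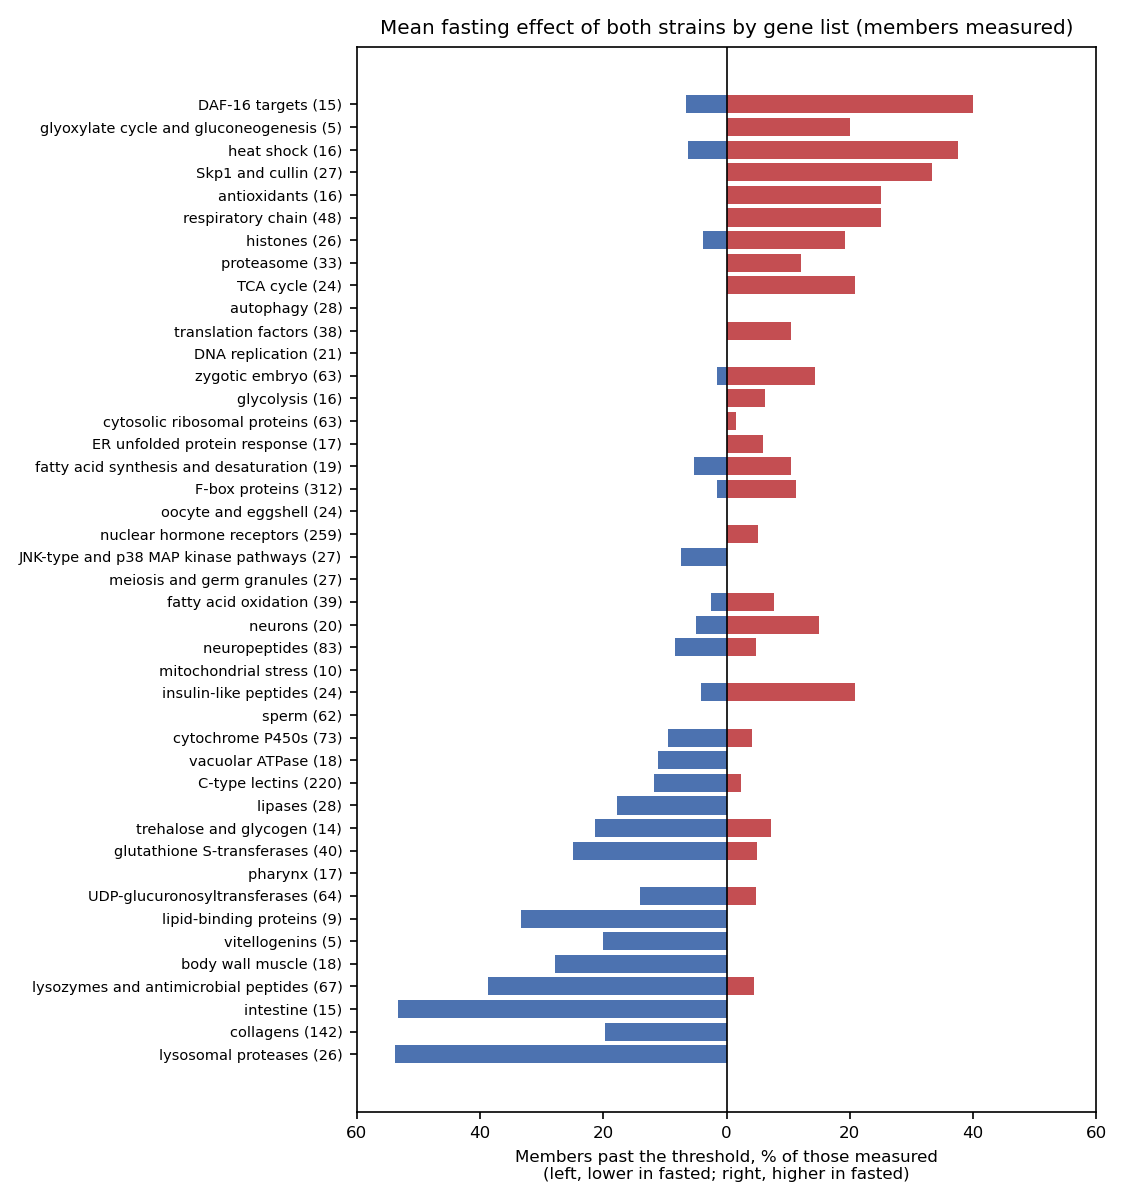
Percent of the measured members of each of the 43 gene lists that were past the threshold in the mean fasting effect, lower to the left and higher to the right. Lysosomal proteases (14 of 26 lower) and intestine markers (8 of 15 lower) stand out on the left, and DAF-16 targets (6 of 15 higher), heat shock genes (6 of 16) and Skp1-related and cullin genes (9 of 27) on the right.

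In the mek-1 strain alone the question was which genes answered to fasting in 3 against 3 arrays. Large increases were seen in T22F3.11 (4.72 ± 0.34, log2, SE), F46C5.1 (3.70 ± 0.35), C35C5.8 (2.65 ± 0.34), far-7 (2.62 ± 0.32) and best-1 (2.57 ± 0.26). The gene acs-2 rose by 2.92 ± 0.54 (adjusted p = 0.0184), a call lost in 4 alternatives: without mek-1 fed 1 (0.0667), without mek-1 fed 2 (0.0530), without mek-1 fasted 1 (0.0674) and without mek-1 fasted 2 (0.0692). Large decreases were seen in ctsa-1.2 (-4.85 ± 0.16), hrg-11.2 (-4.58 ± 0.12), ilys-5 (-4.42 ± 0.40), bcf-1 (-4.29 ± 0.46) and dod-19 (-4.19 ± 0.27). In limma 295 probe sets rose and 728 fell (1023). With the block 1749 rose and 1523 fell (3272), and the count was 553 without mek-1 fed 1, 478 without mek-1 fasted 1 and 465 without mek-1 fasted 2. Of the lists, 22 passed, 11 each way, and 0 with an estimated correlation. Collagens (-0.87, adjusted p = 5.5e-27), lysosomal proteases (-0.84, adjusted p = 2.0e-15), intestine markers (-0.92, adjusted p = 8.5e-12) and body wall muscle (-0.92, adjusted p = 3.8e-10) were shifted lower as lists. Of their members 14 of 142, 13 of 26, 8 of 15 and 6 of 18 fell (69, 18, 12 and 13 adjusted over the list alone). In the lysosomal protease list 1 member rose (2 adjusted over the list alone). With an estimated correlation their adjusted p = 0.457, adjusted p = 0.132, adjusted p = 0.132 and adjusted p = 0.457. The meiosis and germ granule list passed with a mean of 0.18 but 0 of 27 members past the threshold (0 adjusted over the list alone; adjusted p = 0.0280, and adjusted p = 0.766 with an estimated correlation), a call lost with median centring (0.0566), without dim probe sets (0.0592), with array weights (0.0627), without mek-1 fed 1 (0.0793), without mek-1 fed 3 (0.591) and without mek-1 fasted 2 (0.433). With the block 86 collagens and 14 body wall muscle genes were lower, and 2 lysosomal protease and 6 meiosis and germ granule genes higher. The meiosis list's mean ran from 0.0415 without mek-1 fed 3 and 0.0772 without mek-1 fasted 2 to 0.29 without mek-1 fasted 3 and 0.33 without mek-1 fed 2.

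In the mlk-1 strain, with 2 against 2 arrays, clx-1 rose most, by 5.59 ± 0.17 (log2, SE), from 6.36 ± 0.18 to 11.95 ± 0.38 (SD, n = 2). T22F3.11 (4.20 ± 0.42), C23G10.11 (3.25 ± 0.32) and hacd-1 (2.98 ± 0.34) rose here too, as did Y57E12B.1 (3.60 ± 0.14) and the NRAMP-type metal transporter smf-2 (2.81 ± 0.09). Large decreases included ilys-5 (-4.58 ± 0.49), ctsa-1.2 (-4.45 ± 0.20), mbug-1 (-4.37 ± 0.50), C14C6.5 (-4.36 ± 0.34) and dod-24 (-4.03 ± 0.37). These genes passed under every setting tried, with an adjusted p of up to 0.0489 for hacd-1. In limma 117 probe sets rose and 192 fell (309), and with the block 742 rose and 574 fell (1316). The count was 200 without mek-1 fasted 1, 122 without mlk-1 fed 2, 100 without mlk-1 fasted 1 and 102 without mlk-1 fasted 2, the lone array of a group being taken to vary like the other groups. Of the lists 23 passed, 13 higher and 10 lower, and 0 with an estimated correlation. Collagens (-0.64, adjusted p = 3.3e-16) and lysosomal proteases (-0.77, adjusted p = 1.3e-10) were shifted lower as lists, and histones higher (0.33, adjusted p = 5.3e-07), a call lost without _s_at and _x_at probe sets (0.637). Past the threshold were 0 of 142 collagens (0 adjusted over the list alone), 4 of 26 lysosomal proteases, lower (13 adjusted over the list alone), and 2 of 26 histones, higher (7 higher and 1 lower adjusted over the list alone). The collagen mean was -0.40 without mlk-1 fed 2. With an estimated correlation their adjusted p = 0.492, adjusted p = 0.430 and adjusted p = 0.430. The heat shock list had a mean of 0.45, with 1 of 16 members higher (5 adjusted over the list alone; adjusted p = 0.00261, and adjusted p = 0.430 with an estimated correlation). With the block 40 collagens and 13 lysosomal proteases were lower, and 9 histones and 5 heat shock genes higher.

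The effects in the 2 strains, which share no array, were set side by side over 17118 genes. They correlated across genes with a Pearson r of 0.757 and a Spearman rho of 0.527, genes not being independent replicates, and 67.7% of genes had the same sign. Past the threshold in both strains were 46 genes that rose, such as T22F3.11 and hacd-1, where 1.32 would be shared by chance, and 139 that fell, such as ctsa-1.2 and spp-4, against 5.48. These chance values take the calls as independent, while both effects came from the same fit with a shared variance per probe set. No gene was past it in opposite directions (0), although 4120 probe sets in mek-1 and 2722 in mlk-1 had an unadjusted p under 0.05 in limma. Of the 835 genes past the threshold in mek-1, 787 (94.3%) had the same sign in mlk-1. The 185 shared genes became 731 with the block, 16 that rose and 103 that fell without mek-1 fasted 1, and in all 72 without mlk-1 fed 2, 55 without mlk-1 fasted 1 and 60 without mlk-1 fasted 2. Without mlk-1 fed 2 the Pearson r was 0.650.

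**Figure D3:**
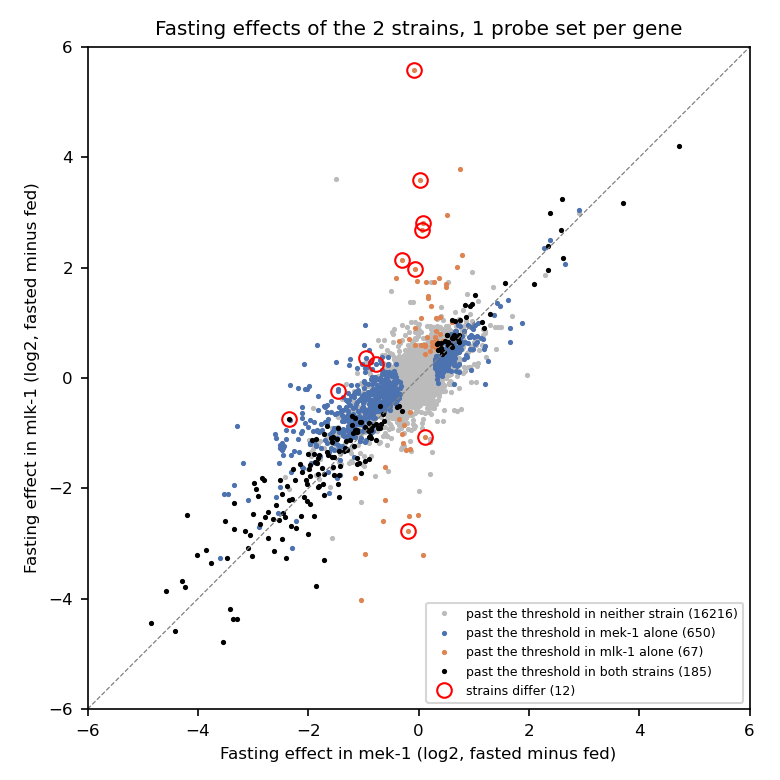
Fasting effect (log2) of each of 17118 genes in mek-1 against that in mlk-1, coloured by where the gene passed the threshold. The 185 genes past it in both strains lie in the quadrants of equal sign, and 12 genes whose effects differed between the strains, clx-1 among them, lie off the diagonal.

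The difference of the fasting effects tested whether the strains answered differently. The genes clx-1, at -5.68 ± 0.22 (mek-1 minus mlk-1, log2, SE), Y57E12B.1 (-3.57 ± 0.18), smf-2 (-2.74 ± 0.12) and Y57E12B.4 (-2.63 ± 0.11) rose in fasted mlk-1 animals, while their effects in mek-1 ran from -0.09 to 0.07. In the other direction, F55G11.8 fell with fasting in mlk-1 animals, where its fed level was 8.24 ± 0.62, against 5.23 ± 0.11 in mek-1, and differed by 2.59 ± 0.31. In limma 3 probe sets were higher and 14 lower (17), all past 2-fold, and 844 had an unadjusted p under 0.05; with the block 7 and 43 passed (50). The count was 7 without mek-1 fed 1, 10 without mek-1 fed 2, 6 without mek-1 fasted 1, 11 without mek-1 fasted 2 and 8 without mek-1 fasted 3. It was 30 without mlk-1 fed 2, 7 without mlk-1 fasted 1 and 7 without mlk-1 fasted 2. The calls of clx-1, smf-2, Y57E12B.1 and Y57E12B.4 held in each of these runs, while that of F55G11.8 was lost with log2(value + 64) (0.134), without mek-1 fed 1 (0.116), without mek-1 fed 2 (0.0598), without mek-1 fed 3 (0.0513), without mek-1 fasted 1 (0.105), without mek-1 fasted 2 (0.0767), without mek-1 fasted 3 (0.0904), without mlk-1 fasted 1 (0.237), without mlk-1 fasted 2 (0.111) and without both mek-1 arrays numbered 3 (0.104).

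Of the lists 14 passed for this difference, 3 higher and 11 lower, and 0 with an estimated correlation. Intestine markers differed by a mean of -0.59 (4 lower adjusted over the list alone, 0 over all probe sets and 3 with the block; adjusted p = 2.5e-06, and adjusted p = 0.430 with an estimated correlation). Meiosis and germ granule genes differed by 0.24 (0 members either way; adjusted p = 2.1e-05, and adjusted p = 0.945 with an estimated correlation). Both lists stayed past the threshold in each alternative other than the estimated correlation, but the meiosis and germ granule value was 0.0987 without mek-1 fed 3, 0.13 without mek-1 fasted 2 and 0.38 without mek-1 fed 2. Body wall muscle genes differed by -0.64 (0 members either way; adjusted p = 4.5e-06, and adjusted p = 0.875 with an estimated correlation), lost without _s_at and _x_at probe sets (0.0602), and by -0.38 without mek-1 fed 3. Histones differed by -0.25 (0 members either way; adjusted p = 4.5e-06, and adjusted p = 0.566 with an estimated correlation), lost without _s_at and _x_at probe sets (0.193). The zygotic embryo list (-0.0839, adjusted p = 0.0343, and adjusted p = 0.945 with an estimated correlation) was lost with quantile normalization (0.0518), with array weights (0.216), without _s_at and _x_at probe sets (0.0878), with replicate block (0.0758), with log2(value + 1) (0.0646), with log2(value), no constant (0.0682), without mek-1 fed 2 (0.0539), without mek-1 fed 3 (0.358), without mek-1 fasted 1 (0.0539), without mek-1 fasted 3 (0.187), without mlk-1 fed 1 (0.425), without mlk-1 fasted 2 (0.715) and without both mek-1 arrays numbered 3 (0.652). Its value ran from -0.17 without mlk-1 fed 2 and -0.14 without mlk-1 fasted 1 to -0.0449 without mek-1 fasted 3, -0.0268 without mlk-1 fasted 2 and 0.00359 without mlk-1 fed 1. Without mek-1 fed 3 the number of lists was 8, and without mlk-1 fasted 2 it was 9.

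Fed animals of the strains were compared to see how the mutants differed with food at hand. Lower in mek-1 was dod-24, at -4.60 ± 0.33 (mek-1 minus mlk-1, log2, SE, 3 against 2 arrays), with F55G11.8 (-3.01 ± 0.22) and the C-type lectin clec-174 (-2.84 ± 0.20) beside the mek-1 transcript (-2.998 ± 0.08). C55C3.3 was higher, by 1.67 ± 0.13. These 5 genes kept their calls in every alternative, with adjusted p up to 0.0437. Other low genes were C17H12.8 (-3.68 ± 0.38) and dod-22 (-2.86 ± 0.28), whose calls were lost in a fit of the fed groups alone (adjusted p = 0.0954 and 0.102). In limma 30 probe sets were higher and 106 lower in mek-1 (136), and with the block, here across strains, 186 and 241 (427). The count was 87 without mek-1 fed 1, 83 without mek-1 fasted 1, 71 without mlk-1 fed 1 and 55 without mlk-1 fed 2.

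In fasted animals the same contrast was led by genes whose fasting effect differed between the strains. They were clx-1 (-5.66 ± 0.16), Y57E12B.1 (-3.59 ± 0.13), smf-2 (-2.81 ± 0.08), Y57E12B.4 (-2.61 ± 0.08) and H02F09.3 (-2.94 ± 0.21), all lower in mek-1, beside hpo-6 (-2.55 ± 0.23) and the mek-1 transcript (-4.03 ± 0.08). Higher in mek-1 were C55C3.3 (1.62 ± 0.13), the microtubule-binding CLASP protein gene cls-3 (1.52 ± 0.14) and arrd-18 (1.16 ± 0.11). In limma 35 probe sets were higher and 295 lower (330), and with the block, again across strains, 394 and 639 (1033). The count was 94 without mek-1 fasted 1, 181 without mek-1 fasted 2, 102 without mek-1 fasted 3, 59 without mlk-1 fasted 1 and 37 without mlk-1 fasted 2.

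Averaged over fed and fasted animals, the insulin-like peptide ins-7 was higher in mek-1, by 1.78 ± 0.25 (log2, SE, 6 against 4 arrays), with C55C3.3 (1.64 ± 0.09), clec-5 (1.60 ± 0.12), cls-3 (1.35 ± 0.10) and fbxa-65 (1.32 ± 0.10). Lower in mek-1 were dod-24 (-3.11 ± 0.24), C17H12.8 (-2.88 ± 0.27), F54F7.2 (-2.88 ± 0.26), clec-174 (-2.40 ± 0.14), the neuropeptide gene nlp-39 (-2.36 ± 0.33) and the hexosaminidase hex-1 (-1.94 ± 0.22). Of 2 probe sets for sek-1, a p38 pathway kinase, the probe set ending in _s_at differed by -2.66 ± 0.07 (adjusted p = 3.5e-07) and the other by 0.32 ± 0.14 (adjusted p = 0.359). Both R03G5.6 probe sets were lower, at -1.93 ± 0.06 and -0.77 ± 0.08. The sek-1 and R03G5.6 probe sets were chosen after their values were seen. The errors and p of this contrast count fed and fasted arrays of the same number as separate, though these shared deviations within a strain. The spread between pairs, 3 in mek-1 and 2 in mlk-1, may be larger, and the block across strains does not model it. The same limit holds for the lists and families of the mean strain difference. In limma 136 probe sets were higher and 551 lower (687), and with the block, here across strains, 679 and 824 (1503). The count was 401 without mek-1 fasted 1, 335 without mlk-1 fed 2, 379 without mlk-1 fasted 1 and 289 without mlk-1 fasted 2.

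**Figure D4:**
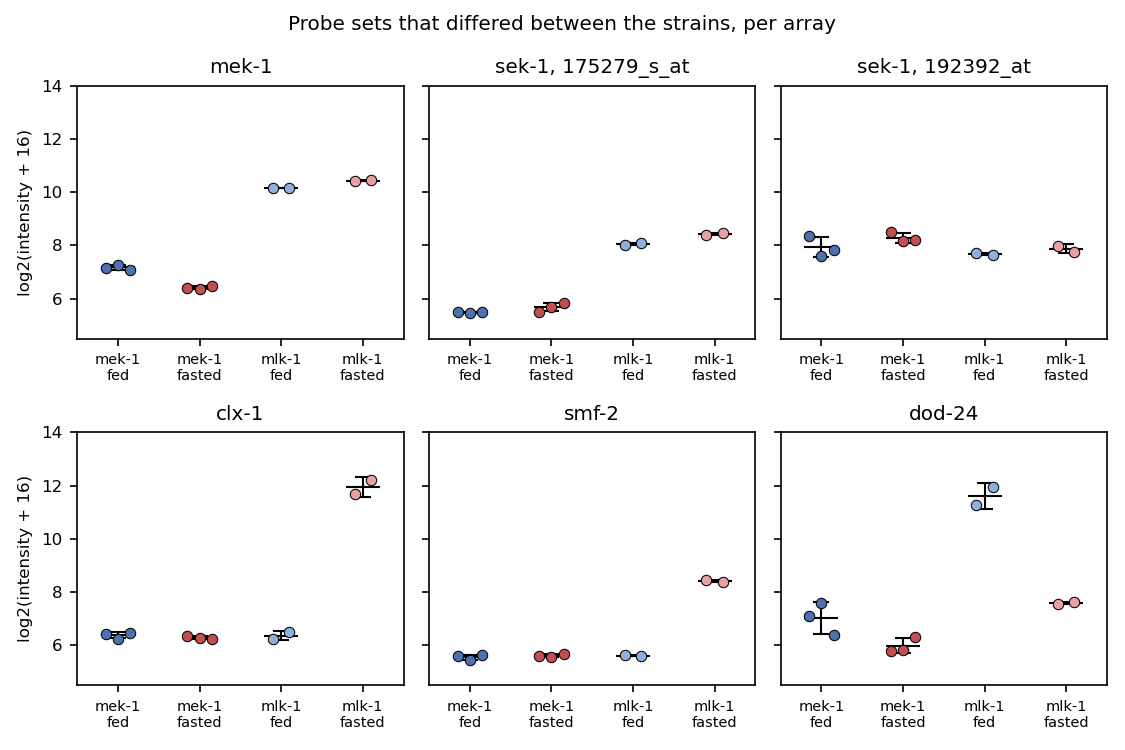
Level on each array, as log2(intensity + 16), of the mek-1 probe set, the 2 sek-1 probe sets, clx-1, smf-2 and dod-24; points are arrays and bars are the group mean ± SD. The mek-1 probe set and the lower sek-1 probe set part the strains on every array, while clx-1 and smf-2 are high on the 2 fasted mlk-1 arrays alone.

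The ubiquitin ligase lists, which were higher with fasting, were lower in mek-1 than in mlk-1. Of 27 Skp1-related and cullin genes, 11 were lower and 0 higher (13 and 0 adjusted over the list alone), such as skr-21, with a mean of -0.35 (adjusted p = 1.1e-07, and adjusted p = 0.384 with an estimated correlation). Of 312 F-box proteins, 44 were lower, such as fbxa-192 (-1.47 ± 0.14), and fbxa-6 and fbxa-65 higher (69 and 5 adjusted over the list alone), with a mean of -0.14 (adjusted p = 1.4e-08, and adjusted p = 0.384 with an estimated correlation). Of 63 early embryo genes 9 were lower (13 adjusted over the list alone), including sdz-25 (-1.47 ± 0.17), with a mean of -0.20 (adjusted p = 2.7e-07, and adjusted p = 0.498 with an estimated correlation). Heat shock genes (-0.29; adjusted p = 0.00366, and adjusted p = 0.480 with an estimated correlation), DAF-16 targets (-0.45; adjusted p = 0.00124, and adjusted p = 0.855 with an estimated correlation), histones (-0.21; adjusted p = 4.4e-07, and adjusted p = 0.480 with an estimated correlation) and autophagy genes (-0.15; adjusted p = 0.00124, and adjusted p = 0.990 with an estimated correlation) were also shifted lower as lists, with 3 of 16, 1 of 15, 2 of 26 and 2 of 28 members lower (6, 2, 8 and 3 adjusted over the list alone, with 1 heat shock gene higher). The DAF-16 target mean was -0.29 without mek-1 fed 3. The histone call was lost without _s_at and _x_at probe sets (0.742) and the autophagy call without both mek-1 arrays numbered 3 (0.0573), a setting chosen after the data were seen. Body wall muscle (0.52; adjusted p = 4.4e-07, and adjusted p = 0.703 with an estimated correlation) and UDP-glucuronosyltransferases (0.18; adjusted p = 4.1e-04, and adjusted p = 0.752 with an estimated correlation) were shifted higher, with 0 of 18 members past the threshold (4 higher adjusted over the list alone) and with 1 of 64 higher and 1 lower (5 and 3 adjusted over the list alone). In all 14 lists passed, 6 higher and 8 lower, and 0 with an estimated correlation. The block ended the calls of sperm (mean 0.18 to 0.0613, adjusted p = 0.00164 to 0.0518), DNA replication (-0.11 to -0.0253, 0.0463 to 0.538), pharynx (0.17 to 0.0337, 0.0463 to 0.625) and collagens (0.24 to 0.00894, 2.3e-05 to 0.767). The same means were reached without both mek-1 arrays numbered 3, since mlk-1 has no array of that number. Over the 23 alternatives other than the estimated correlation the 4 calls were lost in 4, 14, 12 and 3. Of their members 0 passed, apart from 1 collagen, which was lower (and 1 adjusted over the list alone). With the block 1 sperm gene and 2 pharynx genes were higher and 1 pharynx gene lower. Also with the block, 4 histones, 4 autophagy genes and 2 DAF-16 targets were lower, and 6 body wall muscle, 5 UDP-glucuronosyltransferase, 5 F-box and 2 TCA cycle genes higher. The sperm mean was 0.12 without mek-1 fasted 3, and the collagen mean 0.14 without mek-1 fed 3, 0.11 without mek-1 fasted 3 and 0.12 without mlk-1 fed 1. With an estimated correlation these 4 had an adjusted p = 0.995 each. In runs without 1 array, the DNA replication call was lost without mek-1 fed 1 (0.0561), mek-1 fed 3 (0.300), mek-1 fasted 3 (0.238), mlk-1 fed 2 (0.282) and mlk-1 fasted 1 (0.233). Its mean was -0.0669 without mek-1 fed 3 and -0.0716 without mek-1 fasted 3. The pharynx call was lost without mek-1 fed 3 (0.395), mek-1 fasted 3 (0.175), mlk-1 fed 1 (0.0513), mlk-1 fed 2 (0.0672) and mlk-1 fasted 2 (0.148). The pharynx mean was 0.0924 without mek-1 fed 3 and 0.11 without mek-1 fasted 3. Arrays mek-1 fed 3 and fasted 3 stood apart in sperm genes, at 0.30 and 0.33 above the mean of all arrays, and in DAF-16 targets fed 3 was at -1.02. The TCA cycle list was shifted higher (0.09, with 1 of 24 members higher and 3 adjusted over the list alone; adjusted p = 0.0163, and adjusted p = 0.990 with an estimated correlation), a call lost without _s_at and _x_at probe sets (0.434), without mek-1 fed 1 (0.0688), without mek-1 fasted 2 (0.0849) and without mlk-1 fed 1 (0.0513).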

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

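The tests on sek-1, on p38-dependent genes, on the probe sets high in fasted mlk-1 animals and on array mlk-1 fed 1, and the full count of splits that respect the pairs, were chosen after the result was seen. The probe sets and lists given next, and the second pattern below, stood out because the effect of fasting differed between the strains by limma's tests of the difference. The first pattern came from the mean strain difference and the third from the first principal component. Groups of 2 or 3 arrays were not searched for outlying samples.

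Values are the fasting effect in mek-1 minus that in mlk-1 (log2), with the mek-1 and mlk-1 effects where they help. Higher in fasted mlk-1 animals and not in mek-1 were clx-1 (-5.68), Y57E12B.1 (-3.57), smf-2 (-2.74), the 2 probe sets of Y57E12B.4 (-2.63 and -2.24), and a probe set shared by C41G6.13 and Y75B12B.8 (-3.90). Also on that side were H02F09.3 (-2.44), the insulin-like peptide ins-11 (-2.03) and a histone probe set shared by his-10, his-26 and his-14 (-1.198). That histone probe set rose in mek-1 too, by 0.48 against 1.68 in mlk-1. Lower after fasting in mek-1, with smaller effects in mlk-1, were dod-23 (-1.60; -2.35 against -0.75), F59B1.2 (-1.23) and pqn-52 (-1.05), and B0348.2 (-1.31) had effects of -0.94 and 0.37. The mek-1 probe set itself differed by -1.03, in animals whose mek-1 signal was already low. Genes that went down in mlk-1 alone, from levels that fed mek-1 animals lacked, were a probe set shared by dod-21 and cld-1 (4.83), F55G11.8 (2.59) and F49F1.5 (1.198). The calls of clx-1, Y57E12B.1, smf-2 and Y57E12B.4 held in all alternatives run for them, those of F55G11.8, H02F09.3 and F49F1.5 were lost in 10, 9 and 4 of 22, and the other probe sets were not followed through the alternatives.

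Among gene lists, the mean effect was higher in mek-1 for meiosis and germ granules (0.24), proteasome (0.12) and oocyte and eggshell (0.12). It was lower in mek-1 for body wall muscle (-0.64), intestine (-0.59), fatty acid synthesis and desaturation (-0.30), heat shock (-0.27), histones (-0.25), collagens (-0.23), glutathione S-transferases (-0.21), the JNK-type and p38 pathways (-0.14, a list that holds mek-1 itself), neuropeptides (-0.11), zygotic embryo (-0.0839) and lysosomal proteases (-0.0765). With an estimated correlation all 14 lost their call, with adjusted p from 0.430 to 0.945. Over the 23 other alternatives only meiosis and germ granules and intestine kept theirs throughout. The call was lost in 13 for zygotic embryo (adjusted p up to 0.715), 8 for lysosomal proteases (0.404), 6 each for oocyte and eggshell (0.744) and neuropeptides (0.678), 5 for heat shock (0.0914), and 4 for collagens (0.851). It was lost in 3 each for glutathione S-transferases (0.204) and the JNK-type and p38 pathways (0.0688), 2 for proteasome (0.187), and 1 each for histones (0.193), fatty acid synthesis (0.0914) and body wall muscle (0.0602). The mek-1 arrays numbered 3 carry part of these list values, since body wall muscle stood at 1.19 and collagens at 0.93 on mek-1 fed 3, and without that array 8 lists passed. Single arrays moved several values by over 1.5 times: oocyte and eggshell ran from 0.0124 (without mek-1 fed 3) to 0.23 (without mek-1 fed 2), meiosis and germ granules from 0.0987 to 0.38 (the same arrays), proteasome from 0.0256 (without mek-1 fed 3) to 0.19 (without mek-1 fasted 3), and neuropeptides from -0.21 (without mek-1 fed 2) to -0.0295 (without mek-1 fasted 2). Body wall muscle stood at -0.38 without mek-1 fed 3 and glutathione S-transferases at -0.11 without mlk-1 fed 1. Collagens ran from -0.49 (without mek-1 fasted 3), lysosomal proteases from -0.20 (without mek-1 fed 3) and zygotic embryo from -0.17 (without mlk-1 fed 2) to values above 0 without mlk-1 fed 1 (0.00955, 0.0158 and 0.00359).

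The first pattern weighed is the low sek-1 signal in mek-1, in 1 of its 2 probe sets (-2.66), with both probe sets of R03G5.6. A single deletion reaching from mek-1 to sek-1 is argued against, because the 50 measured genes of the 53 between mek-1 and R03G5.6 had a median strain difference of 0.0522 (3 lower, 0 higher). The other sek-1 probe set stood at 0.32 ± 0.14, but this value was known when the pattern was defined. Which part of sek-1 it reads, and whether it reads other transcripts, is not known, so loss of the sek-1 transcript is not excluded. Of genes known to need the p38 pathway, the 7 not named for a strain difference had a median of -0.95 in fed animals. The lowest of 10000 random lists of matched level was -0.35. Without sysm-1 and lys-2, which were named for fasting, these values were -0.95 and -0.56. Such lists take genes as independent, while genes of a pathway can move together on an array, so they measure no spread between samples. In limma 0 of 7 passed alone (lowest adjusted p = 0.0529, clec-67), irg-5 (0.38) and clec-4 (0.44) went the other way and lys-2 stood at -0.14. In fasted animals the values were -1.19 (sysm-1), 0.03 (irg-4), -0.23 (irg-5), -0.56 (K08D8.5), 0.12 (clec-4), -0.31 (clec-67) and -1.50 (lys-2). The low sek-1 probe set stood at -2.57 fed and -2.75 fasted. A candidate explanation is a second lesion near sek-1 in the mek-1 strain that lowers some p38-dependent genes, but loss of MEK-1 itself may do the same, and no sample carries the one without the other. As a wild type was not analysed, these genes may instead be raised in the mlk-1 strain, and which strain departs from normal cannot be told.

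The second pattern is the group of 6 probe sets high in fasted mlk-1 animals alone. Both fasted mlk-1 arrays exceeded the highest of the other 8 arrays in all 6 probe sets, by 2.17 (log2) at the least. The 6 were taken from probe sets past the threshold in the difference, where a rise on a lone array would hardly pass. That both arrays were high was therefore largely fixed by the choice, and a single deviant array was not tested. The clx-1 difference was still -5.64 with median centring, the one of the normalizations between arrays that shrank it most. Array medians lay close together, so scaling could change this difference little, and no conclusion is drawn from it. A strain-specific answer to fasting and a condition shared by the 2 fasted mlk-1 cultures, such as something present on those plates, may each account for the pattern, and both stay open and untested.

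The third pattern is array mlk-1 fed 1, which lay toward the fasted arrays. If RNA of fasted animals had been mixed in, genes that rise and genes that fall with fasting should give the same share of the way to the fasted state. The shares were 0.250 over 37 rising and 0.457 over 320 falling genes, a gap of 0.206, and pairs of mek-1 fed arrays gave gaps of 0.0819 to 0.335. A mixture and a partly fasted culture therefore cannot be told apart, since the gap lies within the range that unmixed arrays give.

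Because equal numbers pair the samples, the real split was set against splits that respect the pairs. For fasting in both strains, with the strain as a covariate, there are 16 of these, too few for a share under 0.05, and the real one gave 2131 probe sets past the threshold against 1 as the highest other. For the strain difference, with food as a covariate, whole pairs allow 10 splits, again too few, with 634 against 123. Among 100 splits that ignore the pairs, 1, the real one, gave as many in each case (highest other 76 and 123). For fasting in mek-1, 1 of 10 splits, the real one, gave 1023, with 1 as the highest other, and 10 splits cannot reach a share under 0.05. For the number of lists past the threshold chance is not excluded: 11 of 100 splits gave as many as the real 25 (highest other 29), and 2 of the 16 that respect the pairs did (highest other 26).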

How the results depend on the processing

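The settings log2(value) without a constant and without both mek-1 arrays numbered 3 were chosen after seeing the data. Probe sets past the threshold as reported were 1023 for fasting in mek-1, 309 in mlk-1, 1781 for their mean, 17 for their difference, 136 for the strains fed, 330 fasted and 687 on average, with 185 genes shared by both strains. With the replicate block these were 3272, 1316, 4502, 50, 427, 1033, 1503 and 731. With array weights they were 2268 for fasting in mek-1, 510 in mlk-1, 3025 for their mean, 979 for the strains fasted, 1098 on average and 312 shared genes. In a fit of the compared groups alone, fasting in mek-1 gave 615 and the strains fed 13. Without _s_at and _x_at probe sets, with fewer probe sets tested, fasting gave 607 in mek-1, 193 in mlk-1, 1131 for their mean and 11 for their difference, and 5 lists passed for the difference. A minimum of 2-fold, which can only remove calls, left 436 for fasting in mek-1, 439 for the mean, and 67, 122 and 112 for the strains fed, fasted and on average. Without both mek-1 arrays numbered 3, fasting in mlk-1 gave 649, the difference 10 and the shared genes 345. With an estimated correlation 0 lists passed in each of the 5 contrasts tested, against 22, 23, 25, 14 and 14. Leaving out each array in turn gave 465 to 1029 for fasting in mek-1, 100 to 444 in mlk-1, 732 to 1988 for their mean, 6 to 30 for their difference, 55 to 134 for the strains fed, 37 to 457 fasted, 289 to 778 on average and 55 to 263 shared genes. The correlation of the effects between strains ran from 0.650 to 0.765 over these runs, and the lists from 18 to 26 (mek-1), 21 to 26 (mlk-1), 23 to 28 (mean), 8 to 15 (difference) and 12 to 17 (mean strain difference). The strain difference of the mek-1 transcript ran from -3.54 to -3.49 and that of mlk-1 from -0.26 to -0.12. Signs turned in 5 list values of the difference and in 3 genes near 0 in the mean fasting effect. Over the runs without 1 array the zygotic embryo list ran from -0.17 to 0.00359, lysosomal proteases from -0.20 to 0.0158 and collagens from -0.49 to 0.00955, each highest without mlk-1 fed 1. Lysosomal proteases stood at 0.0120 without mek-1 fed 1 and at 0.0766 without _s_at and _x_at probe sets. The mlk-1 gene ran from -0.0674 to 0.0803, kgb-1 from -0.0417 to 0.11 and vhp-1 from -0.0703 to 0.0428. Of 282 results on named genes, those that lost their call in the same direction numbered 16 with quantile normalization, 3 with median centring, 6 without dim probe sets, 19 with the trended and robust variance, 11 with a constant of 1, 25 with 64, 11 with no constant and 19 without both mek-1 arrays numbered 3. In a fit of the compared groups alone it was 18 of 80. Array weights and the block each ended 0 and added 1, 1 probe set per gene ended 0, and leaving out _s_at and _x_at probe sets ended 0 of 173. Runs without 1 array ended 12 (mek-1 fed 3) to 102 (mlk-1 fasted 2). Of 98 list calls, 6 were lost in the same direction with quantile normalization, 3 with median centring, 5 without dim probe sets, 0 with the trended and robust variance, 11 with array weights and 27 without _s_at and _x_at probe sets, where 1 more was lost with its sign turned. A further 5 were lost with the block, 2 with each other constant, 12 without both mek-1 arrays numbered 3, 1 with the mean of a gene's probe sets and 98 with an estimated correlation. Runs without 1 array ended 3 to 19 (mek-1 fed 3), with 1 more turned in sign without mek-1 fed 1 and 3 without mlk-1 fed 1. A minimum change lowers counts by construction, and for the other changes the cause was not tested. Signal over background limits what dim probe sets can show, since 3.12% to 4.98% of probe sets per array lay under 20, near the floor of 16.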

Other observations

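The tests on gene families were chosen after the data were seen. Families were taken from gene name prefixes (233 tested, one-sided Fisher's exact test, Benjamini-Hochberg adjusted) and repeated with quantile normalization, median centring, constants of 1 and 64 and the replicate number as a block.

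Several families outside the gene lists held more genes that fell with fasting, as the mean over both strains, than chance gives. Of 12 nspg genes 8 fell and 0 rose, where 0.483 would by chance (adjusted p = 3.3e-07), and of 8 irg genes, named for a response to infection, 5 fell and 0 rose (adjusted p = 1.4e-04). Of 9 dod genes 5 fell and 1 rose (adjusted p = 2.7e-04), and of 12 lec genes, the galectins, 5 fell and 1 rose (adjusted p = 0.00138). These 4 families passed under all 5 repeats, and with the block 1 irg and 2 lec genes were higher. Of 11 hrg genes 4 fell and 1 rose (adjusted p = 0.0114), which was lost with the block (4 lower, 3 higher, adjusted p = 0.0968). Of 40 ttr genes, transthyretin-related, 8 fell and 1 rose (adjusted p = 0.00291), and of 32 cest genes 6 fell and 1 rose (adjusted p = 0.0224). Both were lost with a constant of 64 (adjusted p = 0.177 and 0.827), and with the block 16 and 10 were lower and 5 and 6 higher (adjusted p = 1.2e-06 and 0.00172). In the other direction 7 of 32 sdz genes rose and 1 fell (adjusted p = 0.0177), which was lost with quantile normalization (0.143), median centring (0.102), a constant of 64 (0.0944) and the block (0.0842).

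Families of ubiquitin ligase adaptors were lower in mek-1 than in mlk-1, averaged over fed and fasted animals. Of 95 fbxb genes 23 were lower and 0 higher, against 2.45 by chance (adjusted p = 4.6e-14), of 44 fbxc genes 11 and 0 (adjusted p = 8.3e-07), and of 19 skr genes 11 and 0 (adjusted p = 2.2e-11). These passed under all 5 repeats, as did the asp proteases (5 of 15 lower and 1 higher, adjusted p = 0.00127), the dod genes (4 of 9 lower and 0 higher, adjusted p = 0.00194) and the sdz genes (7 of 32 lower and 0 higher, adjusted p = 8.2e-04). With the block 1 fbxb and 2 asp genes were higher. The btb family (4 of 18 lower and 0 higher, adjusted p = 0.0335) was lost with quantile normalization (0.411), median centring (0.248), a constant of 64 (0.210) and the block (4 lower, 1 higher, 0.114). Genes of the skr, F-box, asp and sdz families are also members of the gene lists above, so these counts are no separate evidence beside the list results. Members of a family can share probe signal, so they are not independent. Fisher's test counts genes, so its p measures no spread between samples.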
